A study of Mus musculus with 8 samples.

How the data were processed

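Total RNA of tongue epithelium from C57BL/6 mice was prepared with a column micro kit, made into stranded poly(A)-selected libraries and sequenced as paired reads of 51 bp on a NovaSeq6000, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20, cutadapt, STAR 2.5.2b, HTSeq 0.11.2 and the genome build GRCm38. They give no roles, order or settings for these tools. Stranded library preparation is stated, but the strand setting of the counting and the treatment of reads shared by several genes are not given in the sources used here. The value of a gene with a near-identical copy, or of overlapping genes, can therefore hold reads of its partner.

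The labels put 4 libraries in the KrTB group (water) and 4 in the KrTB+DOX group (water with doxycycline at 2 mg/mL). Replicate numbers only name libraries, and no pairing or batch is given. The values used are 1 table of the authors' own comparison of these groups, with 15540 genes and 0 columns of values per library. Depth per library is unknown, and no library could be left out, plotted or compared with another.

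Per the file headers, the authors' deposited table holds limma's output columns. The log2 fold change and the mean expression are on the log2 scale in the authors' deposited table. The mean is in log2 CPM, because 2 raised to it sums to 985251 over the genes. The table's t is a moderated score, deposited by the authors with its p-value and a Benjamini-Hochberg adjusted p-value, and its B score was not used. The limma version, design formula, annotation and low-count filter of the authors are not given in the sources used here. Recomputing the Benjamini-Hochberg values from the deposited p-values differed by at most 6.4e-15. The deposited t and p gave 9.76 total degrees of freedom, with a largest gap of 7.9e-12 among the 196 genes where this could be computed. That equals 6 residual degrees of freedom for 8 libraries in 2 groups plus 3.76 prior ones, if no covariate was fitted. Genes with a date in place of a symbol (21) were kept in all tests and left unnamed.

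From this table the SE of each gene was computed as the fold change divided by t, and 95% confidence intervals from the 9.76 degrees of freedom. The median SE over all genes was 0.12 on the log2 scale and the median width of the interval to either side 0.26. A gene was called at an adjusted p under 0.05, using the adjusted p of limma as deposited, and counts at a fold change of at least 2 were added. A positive fold change was taken as higher in KrTB+DOX because Bmi1 is higher in that direction, and the table itself states no sign. If that reading were wrong, every direction would turn. Gene positions, transcript GC content and length came from GENCODE M21 on GRCm38, the build the notes name. Symbols matched directly for 15085 genes and through 1 RefSeq synonym for 299, while 156 were not found, and 99.0% of genes had GC and length values.

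The design fixed before the data were examined assumed counts or normalized values per library. It planned a quasi-likelihood count model, an exact permutation test for Bmi1, principal components and camera on the fitted model. None of these can be run on a comparison table, so the deposited limma statistics took their place. The fixed gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on normal deviates of the deposited t, with a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment ran over the 35 lists with at least 5 measured members, out of 38 lists fixed before the data were examined. The lists covered Polycomb and Hox genes, developmental regulators, cell cycle and p53, keratinocyte layers, papillae, wounding and taste, signalling pathways, metabolism and stress, interferon and immune genes, the clock, and other cell types. Member counts were made with the adjusted p over all genes and adjusted over the list alone. They cover measured members only. Many fixed members had no value among Hox genes (4 of 39 measured), salivary gland (3 of 25), taste bud (13 of 28), cytokines (16 of 33) and developmental regulators (42 of 87).

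Named genes followed a rule fixed before the data were examined. It takes Bmi1, then the 12 largest increases and the 12 largest decreases among called genes with a mean of at least 1 log2 CPM, leaving out predicted and clone-named genes, and up to 4 members with the smallest p of every list. Bmi1 is itself 1 of the 12 largest increases. The rule's demand that the groups do not overlap needs values per library and could not be applied. Other list members are named where a count needed them, picked after their values were seen, and genes outside the rule and the lists are said to be picked after their values were seen. Some genes that the rule takes are not reported here.

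The list and gene tests were tested on simulated data over 15540 genes. At the deposited SEs, 35.1% of 74 genes changed by 0.5, 72.3% of 65 genes changed by 1 and 100.0% of 61 genes changed by 2 on the log2 scale were recovered, with 2 false calls. All glycolysis and hypoxia genes were moved up by 0.5 and all fibroblast genes down by 0.5. Of these 2 shifted lists 2 were called, with 0 others, and 2 of 50 unchanged tables gave a list call. Smaller list shifts were not simulated. Fewer genes were changed than the 1263 called in the data, so recovery there can differ. The simulated genes were drawn independently, so these runs cannot show how often correlation between genes gives false list calls. Alternatives tried were a filter on mean expression, centring on the median gene, removal of the GC and length trend, a test against a 1.2-fold change and, for lists, a correlation of 0.05, ranks, and leaving out genes held by more than 1 list. Similarity between transcripts was searched with blastn 2.17.0. Summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.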

Results

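RNA was sequenced from the tongue epithelium of C57BL/6 mice carrying K14-rtTA and TRE-FLBmi-1, a pair of transgenes together called KrTB. In this tetracycline-controlled design the keratin 14 promoter, active in basal keratinocytes, drives a transactivator that needs doxycycline to switch on a Bmi-1 construct placed behind its response element. Bmi1 is a subunit of Polycomb repressive complex 1, which marks and silences chromatin. The KrTB group held 4 libraries from mice on water, and the KrTB+DOX group held 4 libraries from mice whose water contained doxycycline at 2 mg/mL. The series' design text describes the 4 libraries of each group as biological replicates. All gene values below come from the authors' deposited table of the comparison of these groups, which covers 15540 genes and was made with limma's moderated statistics. Values per library were not analysed here, so the depth of each library is unknown. The precision of the fold changes varied with mean expression, with a median standard error (SE) of 0.34 on the log2 scale below a mean of 0 log2 CPM (library-scaled read counts), of 0.09 from 4 to 6 log2 CPM and of 0.11 from 8 log2 CPM upward. The smallest change past the threshold was 0.80, 0.21 and 0.25 in these ranges.

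The comparison asked which transcripts of the tongue epithelium differed once doxycycline was given to mice able to express the Bmi-1 construct. Bmi1 itself was 42.8-fold higher in KrTB+DOX in the authors' deposited table (log2 fold change 5.42, SE 0.10, adjusted p = 4.5e-09, mean 8.09 log2 CPM). As sets, genes of glycolysis and the hypoxia response and genes of DNA replication and mitosis were shifted upward relative to other genes. So was a joint list of immediate early and heat shock genes, in which Hsp90aa1 was the only heat shock gene called. The sets of interferon response, fibroblast matrix and, by smaller amounts, skeletal muscle genes were shifted downward. Of the 15540 genes of the authors' deposited table, 1263 (8.13%) had an adjusted p under 0.05, of which 593 were higher and 670 lower in KrTB+DOX. At least 2-fold changes made up 311 of these, 137 higher and 174 lower, and 443 of the 1263 changed by less than 0.5 on the log2 scale. Tested against a 1.2-fold change, 222 genes passed, among them 162 with at least 2-fold changes. Tested against no change but only over genes with a mean of at least 1 log2 CPM, 205 genes passed with at least 2-fold changes. The 162 genes named by rule include genes that were not called, and 54 of the called ones lost their call against a 1.2-fold change. The sign of the deposited fold changes was read from Bmi1 itself, since the table names the groups only as control and perturbation. Both groups carry the transgenes, and a group given doxycycline without them was not analysed here, so the comparison covers doxycycline and the Bmi-1 construct together.

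**Figure D1:**
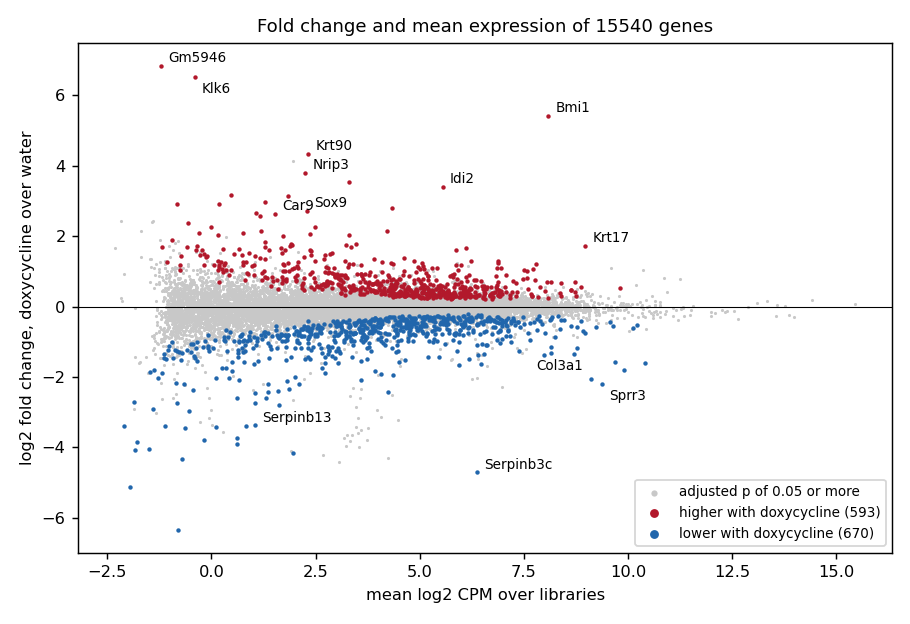
Log2 fold change of KrTB+DOX over KrTB (y axis) against mean log2 CPM over the libraries (x axis) for the 15540 genes of the authors' deposited table, with 593 genes higher (red), 670 genes lower (blue) and the remainder grey at an adjusted p of 0.05 or more. Bmi1 stands apart among abundant genes at a log2 fold change of 5.42 and mean 8.09 log2 CPM.

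Bmi1 lies on chromosome 2 from 18677018 to 18686629 on the plus strand of GRCm38 (ENSMUSG00000026739.13). Reads of the construct and of the resident gene were not separated in its value. The nearby Commd3, picked after its values were seen, had a log2 fold change of -0.18 (SE 0.06, adjusted p = 0.114) in the authors' deposited table.

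After Bmi1, the largest increases among genes averaging at least 1 log2 CPM included keratins, stress genes and a transcription factor. The type II keratin Krt90 was 20.3-fold higher (log2 fold change 4.34, SE 0.38, adjusted p = 7.1e-04) and the epidermal differentiation keratin Krt1 was 6.24-fold higher (2.64, SE 0.29, adjusted p = 0.00163) in the authors' deposited table. Nrip3 was 14.0-fold higher in the authors' deposited table (log2 fold change 3.81, SE 0.23, adjusted p = 6.6e-05). Pmaip1, which encodes the pro-apoptotic protein Noxa, rose 8.77-fold in the authors' deposited table (log2 fold change 3.13, SE 0.31, adjusted p = 0.00116). Sox9, a transcription factor of progenitor cells in many epithelia, rose 6.58-fold in the authors' deposited table (log2 fold change 2.72, SE 0.25, adjusted p = 0.001). The authors' deposited table also listed higher Mgarp (log2 fold change 2.97), the activity-regulated gene Arc (2.79), the hypoxia-induced carbonic anhydrase Car9 (2.63) and the myosin heavy chain Myh7b (2.58). Wide intervals belonged to Idi2, an isopentenyl diphosphate isomerase (log2 fold change 3.40, 95% interval 1.62 to 5.18), and the pseudogene Rpl10a-ps2 (3.53, 1.98 to 5.08) in the authors' deposited table. These last genes lie 11885 bp apart on chromosome 13, on opposite strands, and Idi2 no longer passed when tested against a 1.2-fold change.

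Serpin and cornified envelope genes were among the largest decreases. The squamous cell serpin Serpinb3c was 26.0-fold lower (log2 fold change -4.70, SE 0.57, adjusted p = 0.00233) and Serpinb13 10.4-fold lower (-3.37, SE 0.35, adjusted p = 0.0013) in the authors' deposited table. The small proline-rich proteins Sprr2b (log2 fold change -2.35, SE 0.40) and Sprr3 (-2.19, SE 0.43) fell as well, Sprr3 with a mean of 9.37 log2 CPM over both groups in the authors' deposited table. Metabolic enzymes in this group were Acsm1 (log2 fold change -2.81), the retinaldehyde dehydrogenase relative Aldh1a7 (-2.60), the alcohol dehydrogenase Adh6a (-2.45) and the branched-chain aminotransferase Bcat1 (-2.20) in the authors' deposited table. Nlrp10 (log2 fold change -2.43), the neurokinin receptor Tacr3 (-2.41), the anchoring protein Akap5 (-2.39) and Pi15 (-2.21) completed the 12 largest decreases in the authors' deposited table. Neither Adh6a nor Sprr3 passed when tested against a 1.2-fold change. Serpinb3a, Serpinb3c, Sprr2b, Krt6a, Krt6b, Ifit3, Ifit3b and Rpl10a-ps2 have near-identical copies, and their values are uncertain because the handling of shared reads is not given in the sources used here.

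**Figure D2:**
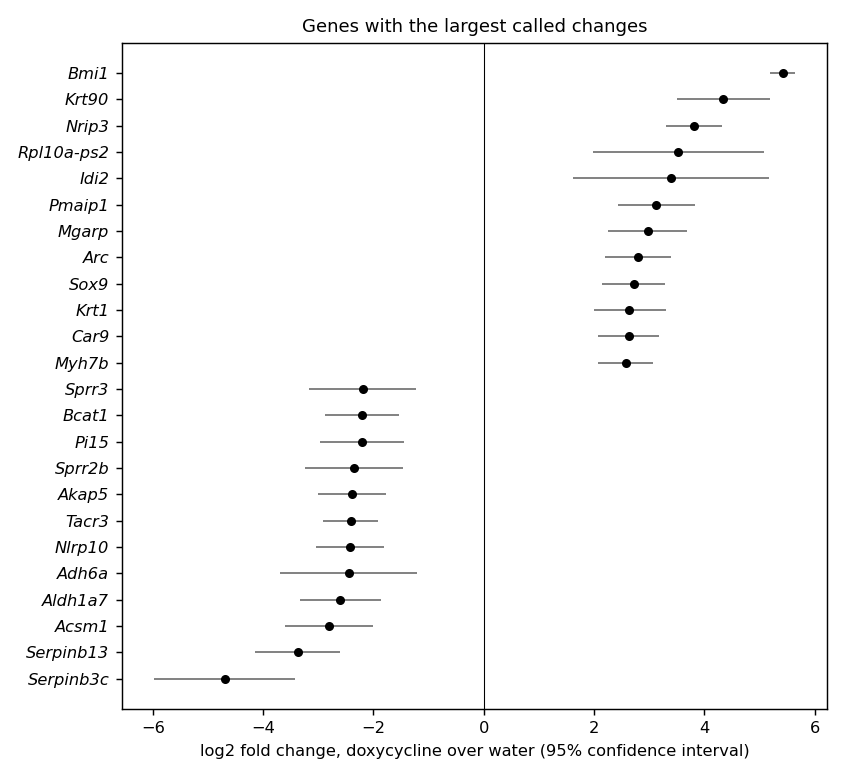
Log2 fold change of KrTB+DOX over KrTB (x axis) with its 95% confidence interval (horizontal lines) for the genes with the largest changes past the threshold in the authors' deposited table, drawn as points. Bmi1 (5.42) has the narrowest interval of those plotted, and Idi2 the widest, from 1.62 to 5.18.

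Keratinocyte genes changed in part. Of 19 genes of the basal layer and its hemidesmosomes, 4 rose and 1 fell (7 and 1 when adjusted over the list alone), with a median log2 fold change of 0.15 and a set test adjusted p of 0.00844. The risers in the authors' deposited table were the basal transcription factor Trp63 (log2 fold change 0.78, SE 0.16), the laminin receptor subunit Itga3 (0.63, SE 0.08), Krt15 (0.54, SE 0.14) and Igfbp2 (1.02, SE 0.20). Sox2, a progenitor transcription factor, fell by 0.64 (SE 0.11) in the authors' deposited table. Krt14, whose promoter drives the transactivator, had a log2 fold change of 0.80 (SE 0.28, adjusted p = 0.11) in the authors' deposited table. The call of the basal list was lost with a preset correlation between genes of 0.05 (adjusted p = 0.0635).

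Of 44 suprabasal and cornified layer genes, 2 rose and 7 fell (3 and 10 when adjusted over the list alone), with no call as a set (adjusted p = 0.191). Decreases included Sprr3, Ecm1 (log2 fold change -0.70, SE 0.11) and the cornified envelope scaffold Evpl (-0.40, SE 0.08), whereas Lce3d was 2.30-fold higher (adjusted p = 0.0187) in the authors' deposited table. The major keratins of the tongue surface, Krt4 (log2 fold change -0.25, adjusted p = 0.328) and Krt13 (-0.29, adjusted p = 0.228), did not pass in the authors' deposited table. Genes of filiform papillae and hair type keratinisation had a median of -0.43 over 28 members, of which 1 rose and 0 fell (the same counts when adjusted over the list alone). The set did not pass (adjusted p = 0.263), but it passed when genes held by more than 1 list were left out (adjusted p = 0.0233). The riser was Padi1, a protein-citrullinating enzyme (log2 fold change 0.76, SE 0.08), whereas Krt33b stood at -2.86 with an SE of 0.89 and an adjusted p of 0.0792 in the authors' deposited table. The stress keratins Krt6a (log2 fold change 0.79, adjusted p = 0.0927) and Krt6b (1.09, adjusted p = 0.073) did not pass in the authors' deposited table.

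Of 22 wound and stress keratinocyte genes 3 rose and 2 fell (5 and 3 when adjusted over the list alone; set adjusted p = 0.269). Krt17, a keratin of injured epithelium (log2 fold change 1.72, SE 0.44), and the interleukins Il1a (0.71, SE 0.16) and Il1b (1.89, SE 0.40) rose, and Serpinb3a (-1.79, SE 0.35) and Serpinb3c fell in the authors' deposited table. Among 13 taste bud genes 2 rose and 1 fell (3 and 3 when adjusted over the list alone; set adjusted p = 0.895). The simple epithelial keratins Krt18 (log2 fold change 2.09, SE 0.25) and Krt8 (1.68, SE 0.44) rose while the transcription factor Prox1 fell by 0.52 (SE 0.12) in the authors' deposited table. The taste receptor Tas1r1 (log2 fold change -1.47, adjusted p = 0.0707) and the calcium channel Itpr3 (0.39, adjusted p = 0.0577) did not pass in the authors' deposited table. For this list the median (-0.16) and the test pointed down while the mean (0.02) lay above 0. Krt8 no longer passed with the GC and length trend removed (adjusted p = 0.0511). Il1b (mean -0.94 log2 CPM), Krt8 (-1.19) and Krt18 (0.76) were expressed at low levels in the authors' deposited table. The sizes of their changes can depend on how counts near 0 were treated.

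Cell cycle genes were shifted upward as sets, while few members passed alone. Of 36 DNA replication genes 33 lay above 0 (median log2 fold change 0.26, set adjusted p = 4.3e-04), and of 36 mitosis genes 33 lay above 0 (median 0.19, set adjusted p = 4.3e-04). For each list the highest set adjusted p over the alternative settings was 0.0296. Alone, 1 replication gene and 2 mitosis genes rose, with the same counts when adjusted over the list alone and 0 lower in either list. These were the flap endonuclease Fen1 (log2 fold change 0.53, SE 0.11), the anaphase ubiquitin-conjugating enzyme Ube2c (0.66, SE 0.15) and the spindle midzone protein Prc1 (0.49, SE 0.11) in the authors' deposited table. Pcna (log2 fold change 0.27), Rfc2 (0.21), Cdc6 (0.60), Cdc20 (0.48) and Ckap2l (0.37) did not pass in the authors' deposited table. Among 9 genes for cyclin-dependent kinase inhibitors and the Rb family, 0 rose and 2 fell (the same when adjusted over the list alone; set adjusted p = 0.263). Cdkn2b, the Ink4 family inhibitor p15, fell by 2.07 (SE 0.28) and Cdkn1c by 0.78 (SE 0.20), while Cdkn1a stood at 0.25 (adjusted p = 0.462) and Cdkn2c at -0.33 (adjusted p = 0.2) in the authors' deposited table. Cdkn2b had a low mean of 0.65 log2 CPM in the authors' deposited table. Cdkn2a, the classical Bmi1 target locus, was among the 10 genes fixed for this list but had no value in the authors' deposited table.

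Of 23 p53 target genes 3 rose and 2 fell (7 and 4 when adjusted over the list alone; set adjusted p = 0.323). Beside Pmaip1, Zmat3 rose (log2 fold change 0.35, SE 0.07) and Eda2r (-0.63, SE 0.12) and Trp53inp1 (-0.38, SE 0.09) fell in the authors' deposited table. With the GC and length trend removed Trp53inp1 had an adjusted p of 0.0576. Of 32 Polycomb complex genes 3 rose and 0 fell, also when adjusted over the list alone, and the set did not pass (adjusted p = 0.142). Beside Bmi1 these were the complex 1 subunits Rybp (log2 fold change 0.64, SE 0.12) and Phc2 (0.36, SE 0.07), while Scml2 stood at -0.71 (adjusted p = 0.0916) in the authors' deposited table. Of 39 fixed Hox genes only 4 had a value. Of these 4 Hox genes 0 passed by limma, also when adjusted over the list alone and at an unadjusted p under 0.05. Their log2 fold changes were 0.33 (Hoxd9), 0.03 (Hoxd8), -0.29 (Hoxc13) and -0.53 (Hoxd4) in the authors' deposited table. Of 87 fixed developmental regulators that Polycomb often silences, 42 had a value. Among these 42, 1 rose (Sox9) and 2 fell, also when adjusted over the list alone (set adjusted p = 0.969). The decreases were Pax7, a marker of muscle satellite cells (log2 fold change -0.79, SE 0.17), and Sox11 (-1.28, SE 0.28) in the authors' deposited table. Sox11 had a low mean of -0.78 log2 CPM in the authors' deposited table.

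Genes of sugar breakdown and of the response to low oxygen were shifted upward as a joint list, with most members past the test alone. Of 25 members 15 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 0.45 and a set test adjusted p of 4.2e-08. Examples in the authors' deposited table were Vegfa (log2 fold change 0.69, SE 0.09), the oxygen-sensing hydroxylase Egln3 (1.04, SE 0.16), the mitophagy receptor Bnip3 (0.61, SE 0.07) and the glucose transporter Slc2a1 (0.90). Glycolytic enzymes were split. Pfkp (0.76), Pgam1 (0.55) and Hk2 (0.46) were among those that rose in the authors' deposited table. Gapdh (0.02), Ldha (0.12), Pkm (0.14) and Aldoa (-0.24) were among those that did not pass in the authors' deposited table. Of 25 immediate early and heat shock genes 6 rose and 0 fell (14 and 0 when adjusted over the list alone), with a median of 0.42 and a set adjusted p of 6.8e-07. Risers included the AP-1 subunit Fosl1 (log2 fold change 1.72, SE 0.29), Atf3 (0.91, SE 0.20), Ier3 (0.60, SE 0.10) and the chaperone Hsp90aa1 (0.55, SE 0.12) in the authors' deposited table. Hsp90aa1 was the only heat shock gene called. Hspa1b (0.26), Bag3 (0.24), Hsph1 (0.22), Hspa1a (0.18), Hspa8 (0.06) and Dnajb1 (0.02) did not pass in the authors' deposited table. Immediate early genes also respond to tissue handling, and collection details per mouse are not given in the sources used here.

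The joint list of cholesterol and fatty acid synthesis genes was lower as a set (28 members, 0 rose and 6 fell, median -0.17, set adjusted p = 0.0119). The counts were 2 and 8 when adjusted over the list alone, and the call was lost with a preset correlation of 0.05 (adjusted p = 0.114). All 6 decreases were of sterol pathway genes. They included Msmo1 (log2 fold change -0.68, SE 0.09), Cyp51 (-0.76, SE 0.13), Fdps (-0.81, SE 0.15) and Hmgcs1 (-0.45, SE 0.07) in the authors' deposited table. Fatty acid synthesis genes went both ways without a call. Fasn (0.22, adjusted p = 0.0763) and Acly (0.22, 0.0849) lay above 0, and Acss2 (-0.37, 0.124) and Elovl6 (-0.18, 0.44) below it in the authors' deposited table. Fasn and Acly were the 2 that rose when adjusted over the list alone. Of 22 retinoid genes 3 rose and 2 fell (4 and 2 when adjusted over the list alone; set adjusted p = 0.263). The retinoic acid degrading enzyme Cyp26b1 (2.38-fold, adjusted p = 0.00968) and Dhrs9 (log2 fold change 0.34, SE 0.09) were among those that rose, whereas the binding protein Crabp2 (-0.76, SE 0.10) and Aldh1a2 (-0.84) fell in the authors' deposited table. Of 27 NRF2 and antioxidant genes 1 rose and 3 fell (3 and 5 when adjusted over the list alone; set adjusted p = 0.661). Aldh3a1, an abundant aldehyde dehydrogenase of surface epithelia (log2 fold change -1.58, SE 0.23), Prdx6 (-1.16, SE 0.18) and Me1 (-0.50, SE 0.13) fell and Srxn1 rose (0.40, SE 0.10) in the authors' deposited table. Me1 had an adjusted p of 0.0563 with the GC and length trend removed.

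Mitochondrial genes did not pass. Of 40 nuclear genes of oxidative phosphorylation 0 passed by limma, also when adjusted over the list alone (3 at an unadjusted p under 0.05, all lower), with a median of -0.07 and a set adjusted p of 0.0696, and the lowest p belonged to Ndufb5 (log2 fold change -0.22, SE 0.09) in the authors' deposited table. Of 10 mitochondrially encoded genes 0 passed by limma, also when adjusted over the list alone (1 lower at an unadjusted p under 0.05; set adjusted p = 0.671), with mt-Cytb at 0.19 (SE 0.14) and mt-Nd6 at -0.45 (SE 0.19) in the authors' deposited table. Their median (0.09) and test pointed up while the mean was -0.00, which includes mt-Atp6 at -1.38 (SE 1.31) in the authors' deposited table. The means of mt-Atp6 (0.19 log2 CPM), mt-Co3 (-0.12) and mt-Co2 (-0.60) were low beside that of mt-Co1 (15.46) in the authors' deposited table. The changes of these low genes were imprecise and say little about mitochondrial RNA. Of 39 ribosomal protein genes 0 passed by limma, also when adjusted over the list alone (2 lower at an unadjusted p under 0.05), with a median of -0.07 (set adjusted p = 0.0696) and Rps4x at -0.23 (SE 0.07) in the authors' deposited table. Of 32 genes of the ATF4 and mitochondrial stress response 2 rose and 2 fell (3 and 3 when adjusted over the list alone; set adjusted p = 0.142). Atf3 and the cystathionine lyase Cth (log2 fold change 0.58, SE 0.13) rose, and the glutathione-degrading enzyme Chac1 (-1.93, SE 0.40) and Stc2 (-0.64, SE 0.17) fell in the authors' deposited table.

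Interferon response genes were shifted downward. None of the 33 members lay above 0, the median log2 fold change was -0.49, and 9 fell while 0 rose (16 and 0 when adjusted over the list alone; set adjusted p = 1.0e-09). The authors' deposited table listed decreases in Rsad2, the antiviral protein viperin (log2 fold change -1.15, SE 0.20), Usp18 (-0.85, SE 0.16), Gbp3 (-0.82, SE 0.18) and Xaf1 (-0.73, SE 0.12). Leukocyte markers did not pass as a set (25 members, 1 rose and 1 fell, also when adjusted over the list alone, median -0.19, adjusted p = 0.241), with the macrophage gene Cd68 lower (-0.60, SE 0.13) in the authors' deposited table. The riser was Epcam (log2 fold change 0.75, SE 0.19), which epithelial cells also express, while S100a8 (0.98, SE 0.47) and Adgre1 (-0.38, SE 0.20) did not pass in the authors' deposited table. Of 10 MHC class II and antigen presentation genes 0 passed by limma, also when adjusted over the list alone (1 higher and 2 lower at an unadjusted p under 0.05; set adjusted p = 0.895), with H2-Ab1 at 0.42 (SE 0.16) and H2-DMa at -0.45 (SE 0.16) in the authors' deposited table. Of 16 cytokine and chemokine genes 2 rose and 0 fell, also when adjusted over the list alone (set adjusted p = 0.969). These were the epithelial chemokines Cxcl14 (log2 fold change 1.70, SE 0.27) and Cxcl16 (0.74, SE 0.17) in the authors' deposited table, while the median of the list was -0.05, its mean 0.07 and the test pointed up.

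Developmental signalling lists did not pass as sets. Of 11 hedgehog genes 1 rose and 0 fell, also when adjusted over the list alone (set adjusted p = 0.651; median -0.00, mean 0.04, test up). The riser was the transcription factor Gli2 (1.99-fold, adjusted p = 0.0123), with Gli1 at a log2 fold change of 0.32 (adjusted p = 0.218) and Gas1 at -0.23 (adjusted p = 0.248) in the authors' deposited table. Of 24 Wnt genes 2 rose and 0 fell (2 and 1 when adjusted over the list alone; set adjusted p = 0.415). The ligand Wnt10a (log2 fold change 0.73, SE 0.18) and the receptor Fzd7 (0.27, SE 0.06) rose, and Axin2 (0.34, adjusted p = 0.0739) and Wnt4 (-0.37, adjusted p = 0.0546) did not pass in the authors' deposited table. With the GC and length trend removed Wnt10a had an adjusted p of 0.0662 and Wnt4 one of 0.0404. Of 15 Notch genes 0 passed by limma, also when adjusted over the list alone (1 higher at an unadjusted p under 0.05; set adjusted p = 0.877; median -0.01, mean 0.02, test up), with Jag2 at 0.23 (SE 0.07) in the authors' deposited table. Of 23 genes of epithelial-mesenchymal transition and invasion 1 rose and 3 fell (3 and 6 when adjusted over the list alone; set adjusted p = 0.606; median and mean 0.01, test down). Zeb1 (log2 fold change -0.34, SE 0.08), Tgfbi (-0.51, SE 0.14) and the matrix protein Sparc (-1.17, SE 0.14) fell and Epcam rose in the authors' deposited table. Of 18 circadian clock genes 0 rose and 7 fell (6 and 9 when adjusted over the list alone; set adjusted p = 0.122). The decreases included the clock output factor Dbp (log2 fold change -1.04, SE 0.11), Bhlhe41 (-0.79, SE 0.11), Per3 (-0.58, SE 0.12) and Ciart (-0.55, SE 0.11) in the authors' deposited table.

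Of the other cell types, the fibroblast and skeletal muscle lists passed the set test. Of 20 fibroblast genes 0 rose and 11 fell (0 and 17 when adjusted over the list alone), with a median log2 fold change of -0.93 and a set adjusted p of 8.1e-11. The fibrillar collagens Col3a1 (log2 fold change -2.05, SE 0.26), Col1a2 (-1.31, SE 0.18) and Col5a1 (-1.36, SE 0.20) fell with Sparc in the authors' deposited table, whereas the proteoglycan gene Dcn stood at -0.15 (SE 0.14). Sparc and Twist2 also belong to the transition and invasion list. Of 30 skeletal muscle genes 29 lay below 0, with a median of -0.22 and a set adjusted p of 4.3e-04. Its highest value over the alternative settings was 0.0296. If muscle genes vary together between libraries more than preset, these set p-values are too small. The calcium-binding Casq1 fell (log2 fold change -0.86, SE 0.12) and 0 rose, the same counts when adjusted over the list alone, while Pvalb (-0.91, SE 0.27), Mybpc1 (-0.31, SE 0.12) and Tnnt3 (-0.28, SE 0.11) did not pass in the authors' deposited table. Muscle RNA was abundant in this tissue, with Myh4 at a mean of 13.56 log2 CPM beside 13.98 for Krt13 in the authors' deposited table. These shifts in fibroblast and muscle transcripts accompanied every keratinocyte, metabolic and interferon change described above.

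Of 16 endothelial genes 2 rose and 2 fell (4 and 2 when adjusted over the list alone), with a median of 0.05 and a set adjusted p of 0.269. Plvap (log2 fold change 0.79, SE 0.10) and Eng (0.42, SE 0.11) rose and Cdh5 (-0.38, SE 0.10) and Prox1 fell in the authors' deposited table. Eng had an adjusted p of 0.0661 with the GC and length trend removed. Of 14 nerve and Schwann cell genes 0 passed by limma, also when adjusted over the list alone (1 lower at an unadjusted p under 0.05; median -0.31, set adjusted p = 0.146), with the myelin gene Pmp22 at -0.48 (SE 0.22) in the authors' deposited table. Of 8 adipocyte genes 1 rose and 0 fell (2 and 0 when adjusted over the list alone; set adjusted p = 0.359), namely Cidea (log2 fold change 0.62, SE 0.16) in the authors' deposited table. Of 7 red blood cell and melanocyte genes 0 passed by limma, also when adjusted over the list alone and at an unadjusted p under 0.05 (set adjusted p = 0.969; median -0.10, mean -0.03, test up), with Tyrp1 at 0.74 (SE 0.41) in the authors' deposited table. Of 3 salivary gland genes 0 passed by limma (1 higher when adjusted over the list alone and at an unadjusted p under 0.05; median 0.32, mean -0.37), with Amy1 at 0.46 (SE 0.15) and Ltf at -1.88 (SE 1.47) in the authors' deposited table. The sex-linked list had 1 measured member, Xist, at -0.09 (SE 0.14, adjusted p = 0.72) and a mean of 9.53 log2 CPM in the authors' deposited table. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no value, and the sex of the mice is not in the labels. Set tests covered the 35 lists with at least 5 measured members, of which 9 passed, 5 upward and 4 downward. An estimated correlation between genes needs values per library, so only preset correlations were used. For any list whose genes vary together more than preset, the set p-value is too small.

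**Figure D3:**
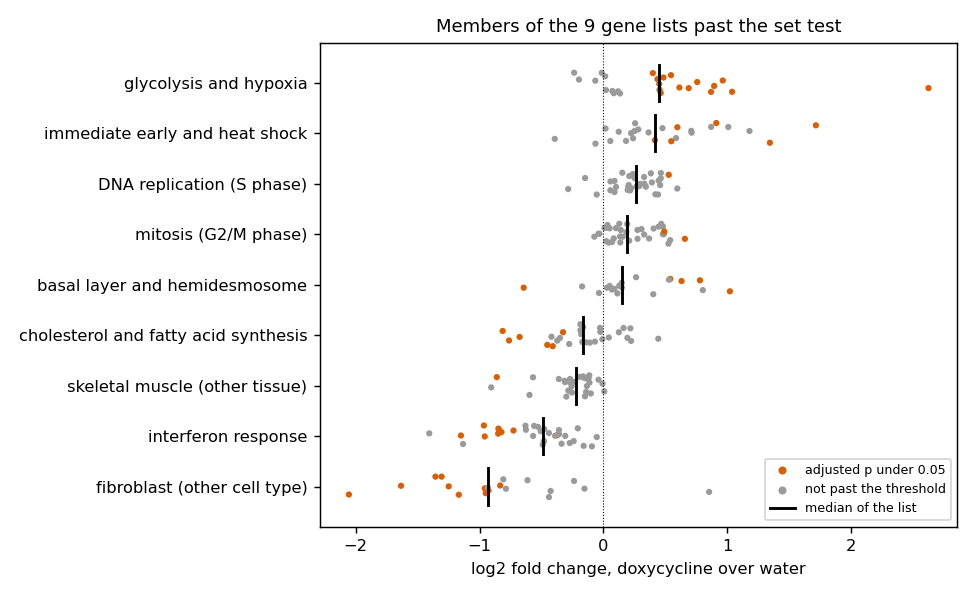
Log2 fold change of KrTB+DOX over KrTB (x axis) for each measured member of the 9 gene lists past the set test (y axis), with members at an adjusted p under 0.05 in orange, others in grey and the list median as a vertical bar. The medians run from 0.45 for glycolysis and hypoxia to -0.93 for fibroblast genes.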

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

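The alternative that left out genes held by more than 1 list was planned; the others were chosen after seeing the data. Values per library were not analysed here, so what had been fixed beforehand beside it was not run: other normalizations, low-count filters, other count models, voom with quality weights, covariates, pseudocounts, fry, an estimated correlation, leaving out each library and other splits of the samples. No paired analysis was possible because the groups share no replicate numbers beyond accession order. The 1263 calls became 222 in the test against a 1.2-fold change, and the 311 calls of at least 2-fold became 162 there and 205 with a mean of at least 1 log2 CPM, where fewer genes were tested. The stricter null hypothesis removes small changes by its construction. The filter, centring and trend removal gave 1185, 1284 and 1162 calls, of which 1122, 1244 and 1053 were shared with the 1263. Bmi1 kept its direction and its call in all of these, between 5.42 and 5.48. The 162 genes named by the rule include genes without a call, which had none to lose. In the test against 1.2-fold 54 lost the call. With the GC and length trend removed 5 lost and 2 gained it (Pcna, adjusted p = 0.0346, and Wnt4). With centring 0 changed side, and none reversed. The 9 list calls were also made with centring, trend removal and the filter. With a correlation of 0.05 there were 7, without the basal and cholesterol lists. Leaving out shared genes added filiform papilla genes (adjusted p = 0.0233, range over alternatives 0.0233 to 0.459), and ranks added oxidative phosphorylation and ribosomal proteins (0.0254 each, range 0.0254 to 0.332). The causes were not tested. Precision limited calls at low expression, where the median SE below 0 log2 CPM was 0.34 against 0.12 over all genes.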

Other observations

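The tests in this part, other than the set test of the fixed clock list, were chosen after the values of the table had been seen, and genes named here outside the fixed lists were picked after their values were seen. Genes were also grouped by the stem of their symbol, and 245 such families with at least 8 members were tested with limma's cameraPR, of which 5 passed. Collagen genes were shifted downward as a family (40 genes, 1 rose and 18 fell, median log2 fold change -0.71, adjusted p = 2.4e-07), a family that includes the collagens of the fibroblast list. Col24a1 (log2 fold change -1.04, SE 0.10) and the basement membrane collagen Col4a5 (-0.80, SE 0.12) fell while Col13a1 rose (1.76, SE 0.21) in the authors' deposited table. All 22 keratin-associated protein genes, which build hair and other hard keratin structures, lay below 0 with a median of -3.12 (adjusted p = 2.4e-07), although only Krtap6-2 passed alone (-3.38, SE 0.75, at a mean of -2.09 log2 CPM) in the authors' deposited table. Their single-gene errors were wide, as for Krtap9-1 (log2 fold change -4.40, SE 1.30, adjusted p = 0.0679) in the authors' deposited table. At a correlation of 0.05 the family had an adjusted p of 9.7e-04. Without values per library, the correlation among these genes could not be estimated. If they vary together between libraries more than preset, both family p-values are too small.

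Serpin clade B genes were shifted downward as a family (18 genes, 0 rose and 7 fell, median -0.55, adjusted p = 0.00164), with Serpinb7 (log2 fold change -1.15, SE 0.26), Serpinb11 (-0.68, SE 0.15) and Serpinb1a (-0.61, SE 0.12) beside Serpinb3c and Serpinb13 in the authors' deposited table. Kallikrein proteases, which include enzymes of epidermal shedding, were shifted upward (13 genes, 3 rose and 0 fell, median 0.33, adjusted p = 0.00371). Klk6 had a log2 fold change of 6.52 (SE 0.58, adjusted p = 7.8e-04) at a mean of only -0.40 log2 CPM in the authors' deposited table. The size of this Klk6 change depends on how counts near 0 were treated. Klk7 rose by 1.09 (SE 0.14) at a mean of 6.95 log2 CPM over both groups in the authors' deposited table. Genes of ribosomal RNA processing named Rrp were higher as a family (8 genes, 0 passed alone by limma and 5 at an unadjusted p under 0.05, median 0.24, adjusted p = 0.0101). The serpin, kallikrein and Rrp families each had an adjusted p of 0.0467 at a correlation of 0.05. The median of all genes was -0.006 and the GC and length correction ran from -0.14 to 0.20, smaller than each of these medians. For Rrp genes the largest correction (0.20) is close to the median (0.24), and no family was tested with the trend removed. Arhgef16 rose by 1.75 with an SE of 0.09 (adjusted p = 1.9e-05) in the authors' deposited table.

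Of 502 genes on the X chromosome 5 rose and 27 fell, against 585 and 635 of 14844 autosomal genes (Fisher's exact test of direction, two-sided p = 2.3e-04, treating genes as independent). Among 20 chromosomes tested with cameraPR, the X did not pass at the preset correlation of 0.01 (adjusted p = 0.121) and passed at a correlation of 0 (adjusted p = 6.5e-10), as did chromosomes 3, 7, 8, 9 and 17. More genes fell than rose also on chromosomes 9 (49 and 18), 6 (54 and 24) and 3 (53 and 28). The median of X genes was -0.07, and -0.03 with the GC and length trend removed, when 6 rose and 24 fell.

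Gm5946, on chromosome X from 150220716 to 150226021 on the minus strand of GRCm38, had the largest increase of the genes named here (log2 fold change 6.83, SE 0.36, adjusted p = 2.8e-05), at a mean of -1.21 log2 CPM in the authors' deposited table. Its longest transcript matched Bmi1 with 97.0% identity over 2658 of its 2724 bases, and the next best gene over 176 bases. Reads of Bmi1 assigned to this copy are a candidate explanation. At this low mean its fold change depends on how counts near 0 were treated, so it was not set against that of Bmi1. Such reads and expression of Gm5946 itself cannot be told apart from these values.

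Fibroblast markers fell by a median of 0.93 on the log2 scale. A uniform loss of fibroblasts as the whole cause is argued against by the spread of the 20 markers beyond their errors (Cochran's Q 145.2, p = 1.8e-21, gene errors taken as independent), with Col3a1 at -2.05 (SE 0.26), Dcn at -0.15 (SE 0.14) and Twist2 at 0.85 (SE 0.42) in the authors' deposited table. An equal loss of all stroma is argued against by 16 endothelial markers with a median of 0.05 (SD 0.34). Skeletal muscle genes had a median of -0.22 (set adjusted p = 4.3e-04). The nerve (-0.31, set adjusted p = 0.146) and leukocyte (-0.19, 0.241) medians were also negative, and the adipocyte median positive (0.30, 0.359). Unequal losses among tissues are therefore not argued against. A GC or length trend is argued against by a fibroblast median of -0.88 (SE 0.17) once it was removed. Loss of a subset of fibroblasts, or markers shared with other cells, stays open. The explanations left open were not tested, nor were others.

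Clock genes had a set test adjusted p of 0.122, with 7 of 18 lower and 0 higher past the test. Adjusted over the list alone, 9 were lower and 6 higher. The set test looks for a shift in a common direction, so it cannot decide whether members moved in opposite directions. The decreases included Dbp (log2 fold change -1.04, SE 0.11), while Arntl (0.68, SE 0.24, adjusted p = 0.109) and Npas2 (0.68, SE 0.22, adjusted p = 0.0923) did not pass in the authors' deposited table. Tissue collected at another phase of the clock in one group is a candidate explanation, and so is a clock shift brought about by the treatment itself. These cannot be told apart, because 0 of the 8 samples have a collection time in their labels. A test of opposed movement within the list is left out, because its groups of genes were assigned after their values were seen.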
